A study of Mus musculus with 6 samples.

How the data were processed

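RNA was taken from freshly isolated retinas of mice at postnatal day 12 with TRIzol, and libraries were made with a stranded TruSeq kit that selects mRNA, per the labels' protocols. Each of the 6 libraries has 1 deposited table with 1 FPKM value (fragments per kilobase of transcript, scaled to library size) for each of 24346 gene symbols. The authors' tools, as listed without their roles or settings in the submitters' processing notes, were TopHat2 2.1.1, Bowtie2 2.3.5.1, Cufflinks 2.2.1 and Cuffdiff, with the genome build mm10. The annotation, the handling of reads that map to several places and the scaling between libraries are not given in the sources used here. No symbol of the mitochondrial genome (mt- prefix) is in the tables, no symbol is blank, and no 2 libraries hold identical values.

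The FPKM values were used as deposited, with no rescaling. Their sums ran from 385962 to 396697 per library, and 13216 to 13298 genes per library had at least 1 FPKM. Spearman correlations between libraries over all genes, which are not independent replicates, ran from 0.983 to 0.987. Read totals are not in the tables, so relative depth was read from the steps of values below 0.3 FPKM, where 1 fragment of a gene is worth a fixed amount within a library. Between 63.5% and 67.0% of the ratios of such values between a library and control 1 were ratios of whole numbers up to 6, within 0.005 on the log2 scale, against at most 3.1% with shifted steps. Relative to control 1, depth ran from 0.807 in triple-deficient 3 to 1.21 in triple-deficient 1. The steps of 107 genes with 1 annotated transcript of at least 2000 bases put control 1 at about 22.5 M fragments (interquartile range 22.1 to 23). On that scale the libraries held about 18.2 to 27.2 M fragments. These depths are estimates, so no counts were rebuilt and no count model was fitted.

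Genotype was compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1) values of the 3 control and 3 triple-deficient libraries. Genes with a mean of at least 0.5 FPKM over the 6 libraries entered the fit, which left 14325 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All changes are on the log2(FPKM + 1) scale, triple-deficient minus control, which understates the change of genes with low values. Intervals are 95% confidence intervals from the same fit. The labels do not say whether the libraries of a group come from separate animals, although the design text speaks of littermates. Xist and Y-linked values put libraries of both sexes in each group, so not all libraries of a group come from 1 animal. Whether each comes from its own animal is not known, so the p-values are taken to cover only the spread between these samples. Control and triple-deficient libraries carry the same numbers 1 to 3, but no label says that a number marks a pair of littermates, so the number was not a term in the model.

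Before the data were examined, 33 gene lists were fixed, covering ganglioside synthesis and degradation, other sphingolipid genes, photoreceptor classes and their regulators, synapse and cilium, retinal cell types, tissues next to the retina, stress, immune and metabolic genes, dividing cells and sex-linked genes. Of these, 32 lists (all but the sex-linked genes) were tested with limma's camera at a preset correlation of 0.01 between genes, and adjusted over the lists. Camera with an estimated correlation and limma's fry, with its directional and its mixed test, were run beside it. The limma p-values of list members were also adjusted within each list alone. That was not corrected for the number of lists, so such calls can arise from looking at many lists. The genes named in the text follow a rule fixed at the same time. They are Ankrd33, Ankrd33b and Nrl, and up to 12 genes with the largest rise and 12 with the largest fall among those with a mean of at least 1 FPKM, an adjusted p below 0.05 and groups that do not overlap. Targeted genes, sex-linked genes and predicted models were left out of that part. Up to 4 members of each list with the smallest p follow, with all measured ganglioside genes. Gnat1, Gnat2, Opn1sw, Snhg1, Gfap, Rpe65, Dct, Cryaa, Cryab, Crygb, Cryge, Crygf, Xist and Ddx3y are outside this rule and were chosen after their values were seen.

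Coordinates are those of NCBI's RefSeq table for GRCm38.p6, which is the mm10 build. It held 23142 of the symbols directly and 1086 as synonyms. GC content and length came from the longest GENCODE M21 transcript of each gene and were known for 99.2% of the genes tested.

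The test was checked on simulated data with the means and the fitted spread of these libraries, 200 of the 14325 genes being changed in each of 5 draws. Over all genes it recovered 23.0% of the 1.25-fold changes, 71.3% of the 1.5-fold changes and 87.3% of the 2-fold changes. Among genes with a mean of at least 5 FPKM the shares were 32.6%, 90.9% and 97.9%. Of all calls in the simulated data, 2.74% were false. The simulated genes varied independently of each other. The Benjamini-Hochberg cut is stricter when fewer genes change, and 4 genes passed in the real data, so recovery there may be lower than these shares.

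Alternatives planned in advance changed the pseudocount, the filter, the scaling, the shrinkage and the weights, added the replicate number as a block, and left out each library in turn. After the data were seen, 3 more were added, with the sex of the library as a covariate, without the genes of small RNAs, and with the trends on GC content and length removed from each library. Figures were drawn with matplotlib 3.10.9. Reads, splice junctions and transcript isoforms were not analysed here.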

Results

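The 6 libraries come from whole retinas of mice at postnatal day 12 that lack Nrl, the transcription factor that directs photoreceptor precursors to the rod fate, so that most of their photoreceptors are cone-like. In 3 control libraries the mice were heterozygous for Panky and for Panky-like, and in 3 triple-deficient libraries both genes were homozygous mutant. Panky is Ankrd33, an ankyrin repeat protein of photoreceptors that acts as a transcriptional co-repressor. Panky-like is taken here to be its paralog Ankrd33b, an assignment that the labels do not state. By estimates from the steps of low values, control libraries 1, 2 and 3 held about 22.5, 24.9 and 23.1 M fragments, and triple-deficient libraries 1, 2 and 3 about 27.2, 21.2 and 18.2 M. Values are FPKM as deposited, given as mean ± SD with n = 3 per group, and changes are triple-deficient minus control on the log2(FPKM + 1) scale, tested with limma.

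The first comparison asks whether the targeted genes differ as the genotypes say. Ankrd33b fell from 33.8 ± 1.45 FPKM in the controls to 1.5 ± 0.265 FPKM in the triple-deficient libraries (SD, n = 3), a log2 change of -3.80 (SE 0.083, limma adjusted p = 4.56e-07), and its mean fell by 95.6%. Ankrd33 fell from 106 ± 2.97 to 55.6 ± 4.66 FPKM, a log2 change of -0.93 (SE 0.064, limma adjusted p = 0.00274), so that 52.2% of its control level remained. All 3 triple-deficient libraries lay below all 3 controls for both genes. Both genes lie on chromosome 15 of GRCm38, Ankrd33b at 31291479 to 31367802 and Ankrd33 at 101115744 to 101120028. The tables hold 1 value per gene, so they do not show which exons the remaining Ankrd33 fragments cover.

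Transcripts of Nrl were present in every library, in groups that do not overlap, at 44.2 ± 5.46 FPKM in controls and 52.5 ± 1.16 FPKM in triple-deficient retinas, a log2 change of 0.25 (SE 0.082, limma adjusted p = 0.861). A value over the whole gene (chromosome 14, 55518978 to 55524981) does not show whether the deleted part is transcribed. Downstream of Nrl, Gnat1, the rod transducin subunit, was at 0.405 ± 0.094 and 0.304 ± 0.054 FPKM in control and triple-deficient libraries, below the filter. Opn1sw, the short-wavelength cone opsin, was at 1545 ± 35.9 and 1474.5 ± 81.5 FPKM. Opn1sw did not differ between the groups (limma adjusted p = 0.958).

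**Figure D1:**
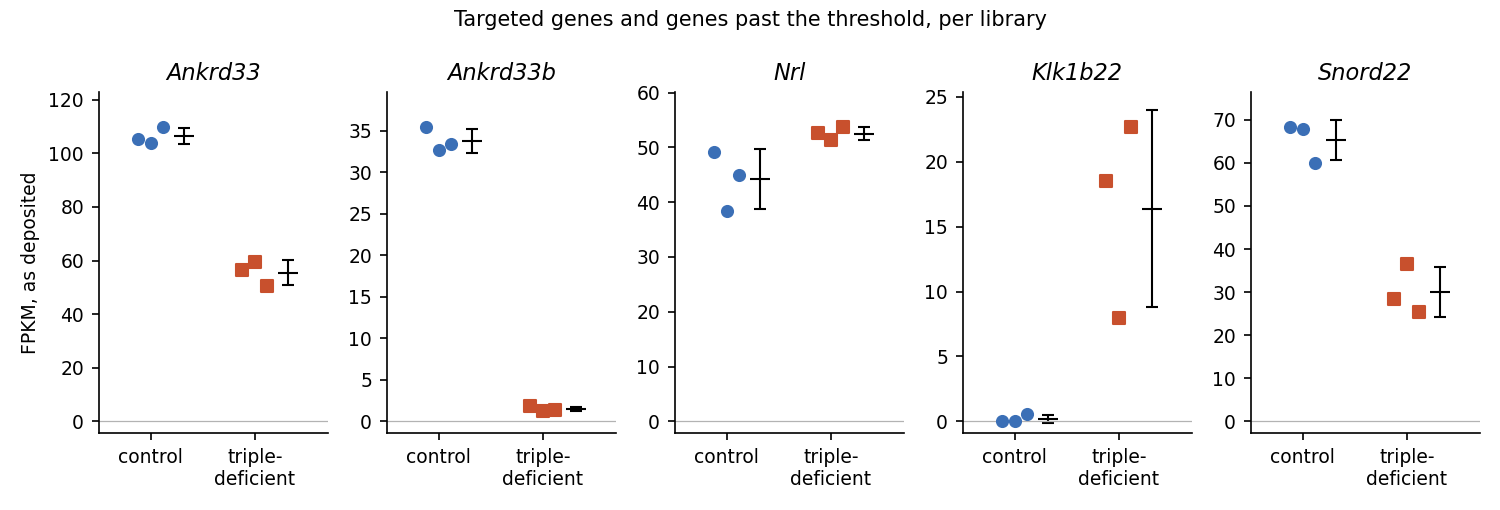
FPKM of the targeted genes Ankrd33, Ankrd33b and Nrl and of Klk1b22 and Snord22 in each library (circles, control; squares, triple-deficient), with the mean and SD of each group as a black bar (n = 3). Ankrd33b drops from 33.8 to 1.5 FPKM and Ankrd33 from 106 to 55.6 FPKM, Nrl is present in all 6 libraries, and Klk1b22 stands at 7.97 FPKM or more in the triple-deficient libraries alone.

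The second comparison covers all genes and asks which others differ between the genotypes. Besides the targeted genes, 1 gene rose and 1 fell. Klk1b22, a gene of the tissue kallikrein family of serine proteases on chromosome 7 (44112673 to 44116922), rose from 0.068, 0 and 0.532 FPKM in control libraries 1, 2 and 3 to 18.5, 7.97 and 22.6 FPKM in triple-deficient libraries 1, 2 and 3. Its log2 change was 3.77 (SE 0.333, limma adjusted p = 0.0126). Snord22, a small nucleolar RNA encoded within the host gene Snhg1, fell from 65.3 ± 4.71 to 30.1 ± 5.80 FPKM, a log2 change of -1.11 (limma adjusted p = 0.0460). Snhg1 itself was at 29.7 ± 3.53 and 32.6 ± 5.15 FPKM. The kit selects mRNA, and Snord22 spans only 8725866 to 8725991 of chromosome 19, so its FPKM may not measure the mature small RNA.

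In all, 4 of 14325 genes tested passed limma's threshold, 1 upward and 3 downward. At an unadjusted p below 0.05 there were 729 genes, 5.09% of those tested, against 716 expected with no difference at all. Genes are not independent, so that number is a loose guide. Other groupings of the 6 libraries into 3 against 3 gave 406 to 862 such genes. With array quality weights there were 1136, and without triple-deficient 1 there were 1028. The groups did not overlap for 1504 genes, 10.5%, where chance gives 10% for 3 against 3 libraries. For 13870 genes, 96.8% of those tested, the 95% confidence interval of the change lay within 1.5-fold of FPKM + 1 in either direction. For genes with low values that allows larger fold changes of FPKM. Of 60 genes with a log2 change beyond 1 in size, 43 were microRNA, small nucleolar or other small RNA genes, 5 were sex-linked, and 3 passed the test. The call of Klk1b22 was lost without control 1 (adjusted p = 0.116), without control 2 (0.0998), with robust shrinkage (0.328) and with no filter (0.128), its log2 change staying between 3.46 and 6.10 and its adjusted p between 0.000311 and 0.328 over all alternatives. Leaving out control 3, triple-deficient 1 or triple-deficient 3 gave 7, 10 and 11 genes. Snord22 lost its call without control 1 (adjusted p = 0.264), control 2 (0.259), control 3 (0.111) or triple-deficient 1 (0.132), and with no filter (0.304), no trend (0.128), robust shrinkage (0.0845) or quantile normalization (0.0530). Its log2 change stayed between -1.25 and -0.99 and its adjusted p between 0.000738 and 0.304 over all alternatives.

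**Figure D2:**
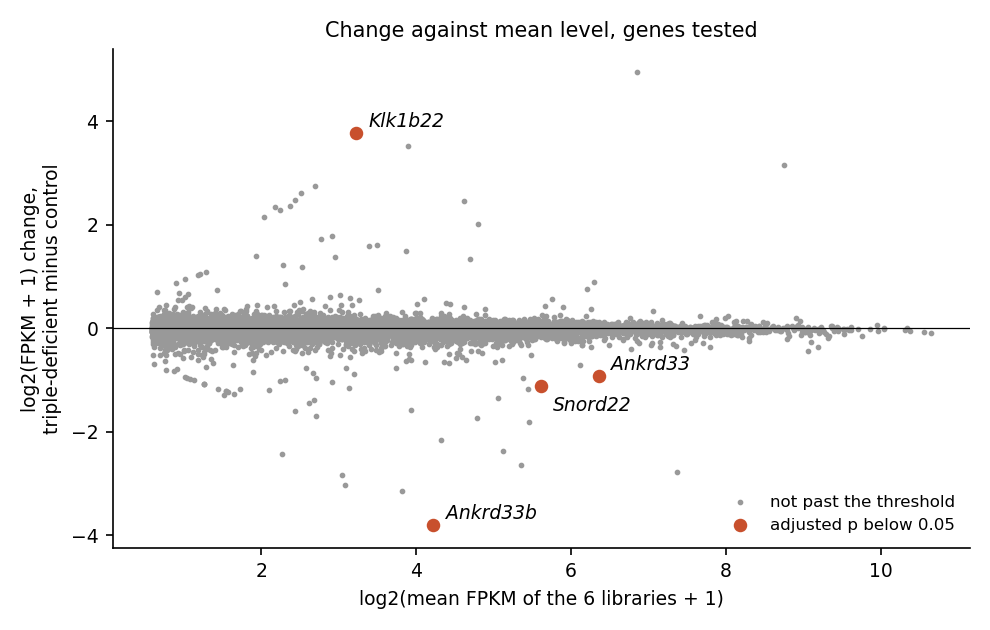
Change in log2(FPKM + 1), triple-deficient minus control, against log2 of the mean FPKM of the 6 libraries plus 1, with 1 point per gene for the 14325 genes tested. The 4 genes past the threshold are named, and the grey points far from 0 are mostly small RNA and sex-linked genes whose libraries vary within the groups.

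The third comparison concerns ganglioside metabolism, which the title of the series names. Gangliosides are glycosphingolipids with sialic acid that are abundant in neuronal membranes. None of the 19 genes of ganglioside synthesis and none of the 14 tested genes of ganglioside degradation changed, either over all genes tested or adjusted over the list alone. Ugcg, which makes the glucosylceramide that gangliosides are built on, was at 21.7 ± 0.320 FPKM in controls and 22.1 ± 0.325 FPKM in triple-deficient retinas. St3gal5, the sialyltransferase of the first ganglioside of the pathway, was at 45.1 ± 1.90 and 43.7 ± 0.580 FPKM, and St8sia1, which adds the next sialic acid, at 4.02 ± 0.236 and 3.94 ± 0.133 FPKM. B4galnt1, which extends these lipids to the complex gangliosides, was at 13.3 ± 0.569 and 12.8 ± 0.469 FPKM.

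Among the synthesis genes, the largest changes were those of B3galt4 (0.10, SE 0.087) and St8sia5 (-0.10, SE 0.082). The list had a median log2 change of -0.02, and its 95% intervals ran from -0.28 to 0.30. On the degradation side, Neu3, a plasma membrane sialidase, was at 5.03 ± 0.293 and 4.50 ± 0.324 FPKM, and Gla, a lysosomal alpha-galactosidase, at 7.0 ± 0.316 and 6.39 ± 0.112 FPKM. Their log2 changes of -0.14 and -0.11 were the largest of that list (limma adjusted p = 0.946 and 0.943). Psap, the precursor of the saposins, was at 278 ± 7.05 and 279 ± 12.7 FPKM. Intervals of the degradation genes ran from -0.30 to 0.21.

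All 33 intervals of both lists lay between -0.30 and 0.30. Neither list held a gene at an unadjusted p below 0.05; the smallest p was 0.279 for synthesis and 0.0889 for degradation in the limma fit. The number of genes past the threshold over all genes stayed at 0 for both lists in each of 20 alternatives. Camera gave adjusted p = 0.764 for each list. Of 33 tested genes of ceramide and sphingomyelin metabolism, 1 changed when adjusted over the list alone. Cers5, a ceramide synthase, fell from 24.0 ± 1.23 to 20.1 ± 0.400 FPKM, a log2 change of -0.25 (SE 0.052, limma adjusted p = 0.0451 over the list and 0.508 over all genes). Cers5 lies on chromosome 15, 1.36 Mb from Ankrd33. Acer2, an alkaline ceramidase, was at 6.44 ± 0.647 and 5.01 ± 0.356 FPKM and did not pass.

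**Figure D3:**
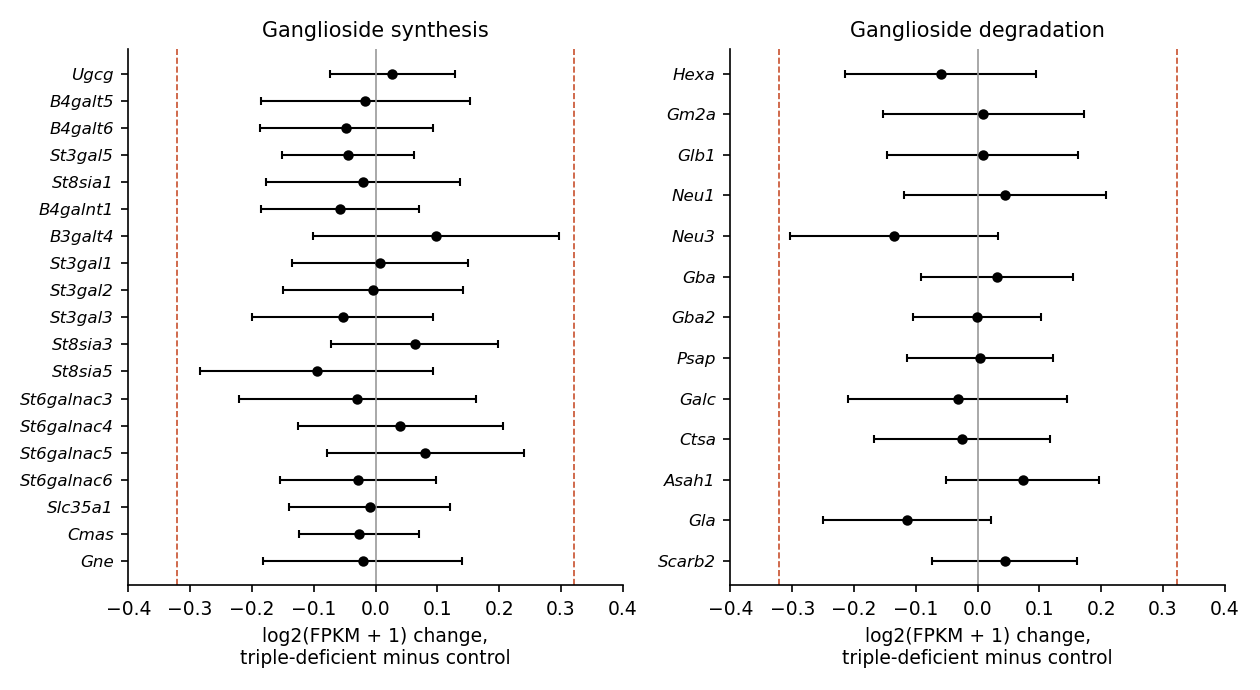
Change in log2(FPKM + 1), triple-deficient minus control, of the 19 genes of ganglioside synthesis and 13 of the 14 tested genes of ganglioside degradation, with 95% confidence intervals from limma (n = 3 per group). All 32 intervals drawn lie between the dashed lines. These lines apply the smallest fold change of the simulated data to FPKM + 1, in either direction. For genes with low values they stand for a larger fold change of FPKM, so that smallest change of FPKM is not excluded for every gene drawn.

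The fourth comparison asks about photoreceptor identity. Rod genes rose as a list, with a median log2 change of 0.11 over 16 tested members (camera adjusted p = 0.0132 at the preset correlation). The call was lost, at adjusted p = 0.916 with an estimated correlation and 0.877 with fry's directional test. Fry's mixed test, which counts changes in either direction, passed for the rod list (adjusted p = 0.0206) and for the ceramide and sphingomyelin list (0.0232), and for no other list. Over all genes no rod gene changed, but adjusted over the list alone, with no correction for the number of lists, 2 rose. Pde6a, a catalytic subunit of the rod phosphodiesterase, rose from 12.8 ± 1.22 to 19.5 ± 2.72 FPKM (log2 change 0.56, SE 0.103, limma adjusted p = 0.0085 over the list and 0.448 over all genes). It passed over all genes with the sex of the library as a covariate (adjusted p = 0.0463; 0.0463 to 0.998 over all alternatives). Susd3 rose from 3.50 ± 0.169 to 5.19 ± 0.782 FPKM (0.45, SE 0.099, limma adjusted p = 0.0139 over the list and 0.553 over all genes). Nr2e3, a nuclear receptor of rods, was at 3.69 ± 0.085 and 4.42 ± 0.179 FPKM, and 7 of the 16 members had changes below 0. The rod list also missed camera's threshold without control 3 (adjusted p = 0.0600), triple-deficient 1 (0.0510) or triple-deficient 2 (0.177), and with no filter (0.0990), its median staying between 0.05 and 0.13.

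Cone genes did not change, with 0 of 20 passing over all genes or over the list alone and 2 at an unadjusted p below 0.05 (median log2 change -0.01, camera adjusted p = 0.916). Gnat2, the cone transducin subunit, was at 562 ± 8.46 and 561 ± 26.5 FPKM, and Pde6h, an inhibitory subunit of the cone phosphodiesterase, at 906 ± 7.37 and 818 ± 67.9 FPKM. Thrb, the thyroid hormone receptor of cones, was at 23.5 ± 1.16 and 26 ± 0.858 FPKM. Slc24a2, the cone sodium, calcium and potassium exchanger, was at 17.1 ± 1.7 and 11.5 ± 5.72 FPKM, and it passed in the fit without triple-deficient 3 (log2 change -0.97, limma adjusted p = 0.0140; 0.0140 to 0.998 over all alternatives).

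Genes shared by rods and cones did not shift as a list (32 tested, median 0.01), and Impg1, a matrix proteoglycan around photoreceptors, was at 24.8 ± 3.78 and 32.2 ± 0.489 FPKM (limma adjusted p = 0.651). Of 22 regulators of photoreceptor fate, Sall3, a zinc finger factor of cones, fell from 14.7 ± 0.362 to 11.7 ± 0.895 FPKM when adjusted over the list alone (log2 change -0.31, SE 0.063, limma adjusted p = 0.0262; 0.508 over all genes). Neurod1 and Rax were at 185 ± 23.9 and 128 ± 4.42 FPKM in controls and at 218 ± 17.2 and 105.5 ± 17.5 FPKM in triple-deficient retinas, and neither passed. The list as a whole had a median of -0.001. Ribbon synapse genes (30 tested, median 0.02) and genes of ciliary transport (34 tested, median 0.01) held no change.

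The fifth comparison asks for signs of stress, glial reaction, inflammation or altered metabolism. None of these lists passed camera's threshold in the main fit. Medians were -0.03 for reactive gliosis and stress (22 tested), -0.05 for microglia and macrophages (20), -0.02 for interferon and antigen presentation (20), 0.001 for cell death (21), 0.01 for the endoplasmic reticulum and integrated stress responses (27), -0.001 for oxidative stress (21), -0.003 for heat shock (14), -0.007 for lysosomal genes (35) and -0.05 for immediate-early genes (17). Gfap, the intermediate filament of reactive Müller cells, was at 10.8 ± 1.28 and 11 ± 1.02 FPKM, and Cebpd, a factor of the gliosis list, at 1.8 ± 0.121 and 0.94 ± 0.38 FPKM (limma adjusted p = 0.990 and 0.651). Slc7a11, the cystine transporter of the stress response, was at 3.98 ± 0.269 and 6.65 ± 2.35 FPKM and passed only without triple-deficient 1 (limma adjusted p = 0.0246; 0.0246 to 1 over all alternatives). Among immediate-early genes, Ier3 fell from 27.5 ± 0.715 to 22.5 ± 0.555 FPKM and Klf2 from 2.28 ± 0.235 to 1.54 ± 0.222 FPKM when adjusted over the list alone (limma adjusted p = 0.0050 and 0.0400; 0.326 and 0.668 over all genes).

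In energy metabolism, Cox5b and Cox8a, nuclear-encoded subunits of cytochrome c oxidase, fell from 249 ± 6.6 to 193 ± 13.6 and from 652 ± 26.4 to 510 ± 48.2 FPKM when adjusted over the list alone, 31 oxidative phosphorylation genes (limma adjusted p = 0.0078 and 0.0220; 0.299 and 0.508 over all genes). That list had a median of -0.02. Medians were 0.03 for glycolysis (23 tested) and 0.05 for cholesterol synthesis (26), whose camera adjusted p of 0.0569 was the smallest of the lists that did not pass. Hmgcs1, of the mevalonate pathway, was at 57.4 ± 2.27 and 64.0 ± 2.43 FPKM. Triple-deficient 3 stood apart from the other libraries in its base composition, its deviations correlating with GC content across genes, which are not independent, at Spearman -0.59, against 0.07 to 0.30 in the others. The change between genotypes itself correlated with GC content at Spearman -0.36 and with transcript length at 0.20. Over all alternatives, removal of these trends among them, log2 changes stayed between -0.41 and -0.31 for Cox5b and -0.42 and -0.27 for Cox8a. They stayed between -0.30 and -0.23 for Ier3, -0.54 and -0.25 for Klf2, -0.36 and -0.26 for Sall3 and -0.28 and -0.21 for Cers5. That argues against the trends as the whole cause of the falls of these genes, although a part may still come from them. The adjustment over these lists alone was not repeated in the alternatives.

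The last lists mark other cells of the retina and neighbouring tissues. Markers of the retinal pigment epithelium fell as a list, with a median log2 change of -0.16 over 13 tested members (camera adjusted p = 0.00353 at the preset correlation). The call was lost, at adjusted p = 0.916 with an estimated correlation, 0.877 with fry's directional test, 0.0606 with no filter and 0.191 without triple-deficient 1, and the median stayed between -0.31 and -0.08. Fry's mixed test gave adjusted p = 0.0832. Adjusted over the list alone, 3 fell. Ttr, a retinol and thyroxine carrier, fell from 15.8 ± 3.26 to 8.81 ± 1.66 FPKM, and the melanosome genes Tyrp1 and Pmel fell from 3.46 ± 0.333 to 1.95 ± 0.399 and from 3.84 ± 1.42 to 1.61 ± 0.173 FPKM (limma adjusted p = 0.0082, 0.0082 and 0.0138; 0.508, 0.472 and 0.651 over all genes). Pmel passed over all genes without control 3 (adjusted p = 0.0233; 0.0233 to 0.998 over all alternatives). Rpe65, the retinoid isomerase of that tissue, was at 2.59 ± 0.60 and 2.32 ± 1.29 FPKM, and Dct, a further melanin enzyme, at 21.3 ± 4.57 and 25.4 ± 5.67 FPKM.

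No list of another cell type passed camera's threshold in the main fit, although up to 7 lists of any kind passed when 1 library was left out. Medians were 0.005 for Müller glia (18 tested), 0.05 for bipolar cells (19), -0.02 for amacrine cells (16), 0.02 for horizontal cells (9), -0.01 for ganglion cells (16), 0.03 for endothelial and mural cells (18), 0.001 for astrocytes and ciliary epithelium (7), 0.02 for blood (4), 0.02 for dividing cells (13) and -0.33 for lens (10). Apoe, abundant in Müller glia, was at 599 ± 30.5 and 499 ± 55.9 FPKM, and Pcp2, of bipolar cells, at 263 ± 7.08 and 287 ± 25.7 FPKM, neither passing. Camera's direction or the mean went against the sign of the median for ganglioside degradation, ceramide, cell death, Müller glia, ganglion cell and astrocyte and ciliary genes, all with medians within 0.03 of 0. Lens transcripts were concentrated in control 1, where Cryaa, a lens crystallin, stood at 4.61 FPKM against at most 0.129 FPKM in the other libraries. Xist was at 322 to 340 FPKM in control 1, control 2 and triple-deficient 2, and the Y-linked Ddx3y at 17.2 to 24.8 FPKM in control 3, triple-deficient 1 and triple-deficient 3, so both groups held libraries of both sexes; none of the 5 tested sex-linked genes passed.

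**Figure D4:**
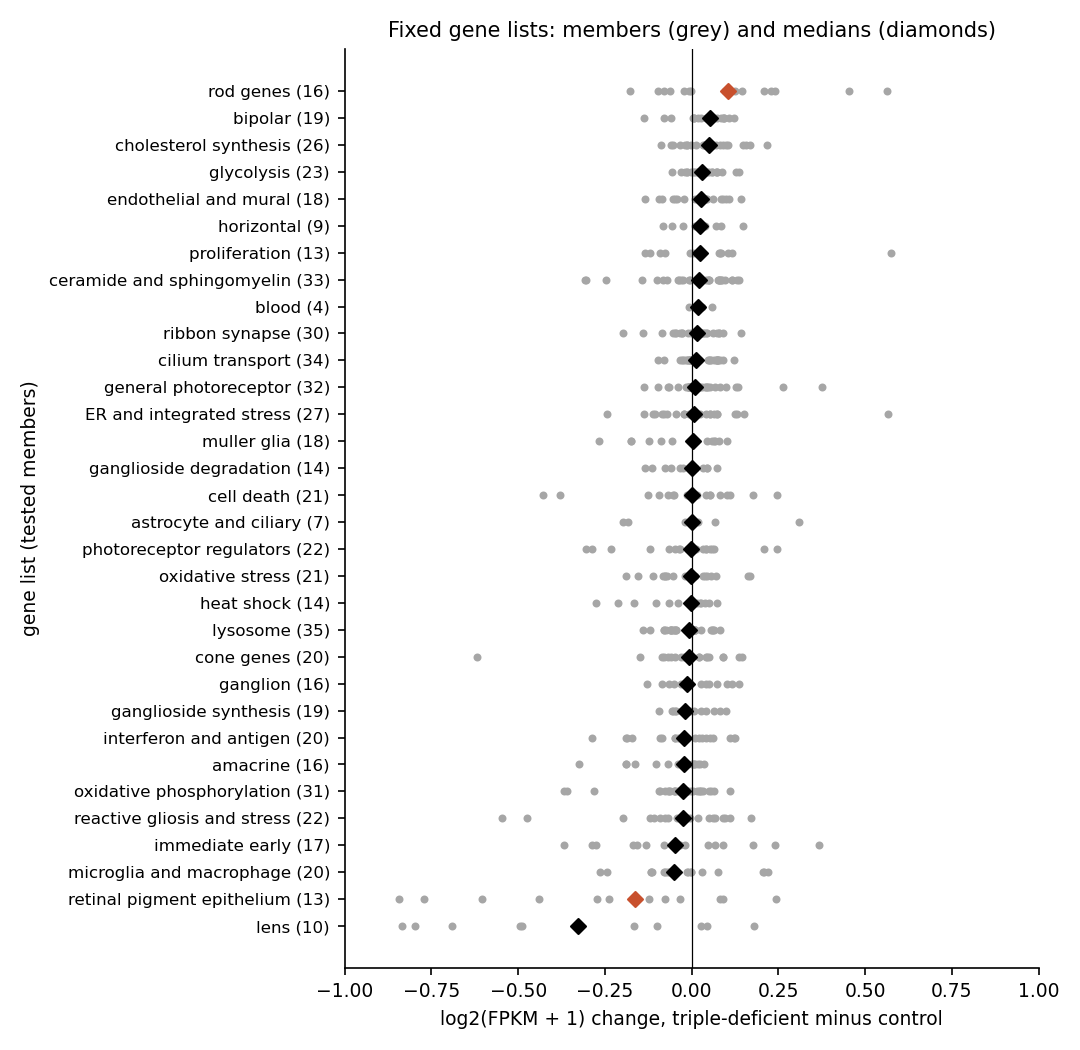
Change in log2(FPKM + 1), triple-deficient minus control, of the tested members of each of 32 gene lists fixed in advance (grey points) and the median of each list (diamonds), with the number of tested members in brackets. Diamonds in orange mark the rod list (median 0.11) and the pigment epithelium list (-0.16), which passed camera at the preset correlation and not with an estimated correlation (adjusted p = 0.916 for both) or fry's directional test (0.877 for both).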

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

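The 17 settings fixed in advance and the 3 added after seeing the data left Ankrd33 (log2 change -0.98 to -0.84) and Ankrd33b (-4.41 to -3.75) past the threshold in all 20, and the 2 counts of changed ganglioside genes at 0. The count of changed genes, 4, fell to 2 with no filter and to 2 with robust shrinkage, which kept Ankrd33 and Ankrd33b, and lay between 3 and 11 when 1 library was left out. The count of shifted gene lists, 2, became 0 with no filter, 0 with an estimated correlation, 0 with fry's directional test, 5 with array quality weights and 4 with the GC and length trend removed, and lay between 0 and 7 when 1 library was left out. The estimated correlation and fry allow for members that vary together; for the other changes the cause was not tested. Of the values of single named genes, 3075 kept their direction and side of the threshold or stayed within their spread, 12 lost a call (4 of Klk1b22 and 8 of Snord22), 4 gained 1 and 7 moved. The change of B4galnt1, -0.06, was 0.033 with the GC and length trend removed, neither passing; the cause was not tested. With the replicate number as a block, 4 genes and 2 lists passed, as without it, and no call of a targeted gene changed. Deviations of libraries with the same number correlated at 0.02, 0.11 and 0.07, and 3 of 6 libraries correlated best with their own number, so the numbers were not taken as pairs. With 3 libraries per group, the smallest simulated changes were mostly missed, 23.0% being recovered, and depth differed 0.807 to 1.21 relative to control 1. With fewer changed genes than the 200 simulated, larger changes can be missed too.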

Other observations

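The tests of genomic windows, family members, sex, GC trend, correlation and regroupings in this part were chosen after the results were seen. Several genes beside Ankrd33 differed between the groups without passing over all genes, and those named here were chosen after their values were seen. Fignl2, 0.05 Mb away, was at 24.1 ± 2.04 FPKM in controls and 16.8 ± 0.038 FPKM in triple-deficient libraries (SD, n = 3; log2 change -0.49, SE 0.064, limma adjusted p = 0.155), and passed without control 3 and with array quality weights. Acvrl1, a receptor of the TGF-beta family 0.02 Mb away, was at 3.53 ± 0.039 and 2.40 ± 0.072 FPKM (-0.41, SE 0.066, limma adjusted p = 0.275). Acvr1b, Mettl7a1 and Cers5 were lower and Slc4a8 was higher within 1.36 Mb, each with groups that do not overlap.

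Within 5 Mb of Ankrd33, 17 of 115 tested genes (14.8%) had an unadjusted p below 0.05, 11 of them lower and 6 higher. That share lay at percentile 97.9 of 2266 overlapping windows of the same width along the genome, whose median was 4.26%, so a difference carried along with the targeted locus, such as flanking sequence from another strain or an effect of the mutant allele on its neighbours, is a candidate explanation. Around Ankrd33b the share was 8.11% of 37 genes, percentile 81.6, although within 1 Mb 3 of 8 genes did so, all higher, which leaves open whether both loci carry such a difference. Chromosome 15 as a whole, both regions included, stood at 7.52%, the highest share of the chromosomes. In 1 of the 10 splits of the 6 libraries into groups of 3, the real one, was the share near Ankrd33 as high, the highest of the others being 9.57%; 10 splits are too few for a share under 0.05. Whether these genes respond to the mutations in the targeted genes was not tested, since genotype and flanking sequence cannot be told apart here.

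For the rise of Klk1b22, near-identical paralogs were looked at first. The highest of 13 other Klk1b genes reached 0.102 FPKM in any triple-deficient library, against 7.97 FPKM or more for Klk1b22, which argues against reads from a risen paralog of the tables. With sex as a covariate its log2 change was 3.46 (limma adjusted p = 0.000311), which argues against the sex of the libraries as the whole cause. Within each group the libraries with Y-linked transcripts had the highest values, and the change without the covariate was 3.77. A part played by sex thus stays open. Within 5 Mb of Klk1b22, 10 of 116 tested genes (8.62%) had an unadjusted limma p below 0.05, percentile 85.6 of the windows. Within 1 Mb the share was 11.1%, percentile 89.2. Chromosome 7 as a whole stood at 7.21%, rank 2 of the chromosomes after chromosome 15. These shares do not settle whether a variant region lies near Klk1b22. A sequence variant at the gene itself that happens to separate the groups, and a response to the mutations in the targeted genes, stay open.

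For the lower pigment epithelium markers, removal of the GC and length trend from each library left a median of -0.18 (camera adjusted p = 0.00338; 6.86e-05 to 0.916 over all alternatives), which argues against that trend as the whole cause. Members of the list varied together between libraries of the same genotype, with a mean correlation of 0.220, at percentile 99.4 of 10000 random lists matched on level (median -0.011). Pigment epithelium carried over in differing amounts at dissection would give this, but so would genes of 1 tissue that are regulated together. Camera's estimated correlation was higher for blood (0.677, 4 tested members) and lens (0.291), lists of tissue that can itself be carried over. It was also higher for glycolysis (0.395), ER and integrated stress (0.284) and bipolar cells (0.233), although lower for most lists. Such a correlation is thus not particular to carried-over tissue, and it does not decide between carry-over and joint regulation. Dct, with a log2 change of 0.24 (SE 0.186), did not go with Ttr, Tyrp1 and Pmel, while Rpe65, at -0.16 (SE 0.243), is not set apart from them. A change within that tissue was not tested and stays open.

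Other splits of the same libraries also called genes. In 2 of 10 splits, the real one included, at least 4 genes passed, and the highest other split gave 11. That split set the libraries with high Xist against those with Y-linked transcripts, so it is a contrast of sex and no measure of chance. Of its genes, 6 were outside the listed sex-linked genes. That list holds only 6 symbols, and whether these genes follow sex was not tested. Apart from that split and the real one, no split gave more than 2 genes. For gene lists, 6 of 10 splits gave at least 2, and the highest other gave 9. The 10 splits are too few for a share under 0.05.

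Control 1 had the highest value of all 14 listed crystallin genes other than Cryab in the tables. Crygb, Cryge and Crygf stood at 3.21, 2.0 and 0.872 FPKM there and were listed at 0 in the other 5 libraries. Cryab, which the retina also expresses, was at 40.0 to 43.9 FPKM in the 6 libraries.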
